A study of Mus musculus with 11 samples.

How the data were processed

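Libraries were polyA-selected RNA of primary palatal mesenchyme cells of mouse embryos at mid-gestation, grown in 10% serum and starved overnight in 0.1% serum, per the labels' protocols. The labels give 11 libraries: 4 starved, 4 after 1 h of PDGFA and 3 after 1 h of FGF1 with heparin. Nothing in the labels says whether replicates came from separate litters or cultures.

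Per the submitters' processing notes, CASAVA, TopHat and Cuffdiff were used with genome build mm10. Their versions, roles and settings, the annotation, and how reads with several matches were handled are not given in the sources used here. The deposited values are FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments), 1 value per group made by the authors from that group's libraries, with a lower and an upper bound per the file headers. The confidence level of the bounds is not stated; they were taken as 95% bounds where a fold interval was computed. FPKM divides by transcript length and library total, so a gene can shift when others change, and rows with near-identical copies depend on how multiply matching reads were assigned. Depth is unknown, since no read counts were used.

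The planned test, limma on log2 values of every library, needs values per library. The table holds 3 group values per row, so that test, its replicate block, the leave-one-out fits and the gene set test camera were not run. Instead a row was called when the deposited intervals of the compared groups did not overlap and each FPKM lay inside its own interval. Both conditions were chosen after the table was seen, the second because single short rows had values outside their own bounds. This is a description of group estimates, not a test between replicates. Rows needed at least 1 FPKM in at least 1 group and no failed estimate: 11702 of 23286 rows passed, and 2 rows had failed estimates. Log2 folds were computed on FPKM + 0.5, which understates the change of low genes, and fold ratios are given only where the denominator was at least 1 FPKM.

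On simulated groups with known folds and interval-wide noise, the rule recovered 38.8% of 2-fold, 89.6% of 4-fold and 98.5% of 8-fold changes for PDGFA against starved cells, over 11286 rows, and called 77 unchanged rows. For FGF1 against starved cells the shares were 55.2%, 98.5% and 95.5%, with 41 unchanged rows called. For FGF1 against PDGFA they were 25.4%, 82.1% and 92.4%, with 34. The real counts were 36, 65 and 14. The 77 exceeds the 36, so the intervals overstate the noise in these values, and these numbers do not give the share of chance calls. The list and trend steps were also tested on simulated data.

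Rows carry RefSeq transcript accessions and a locus. Accessions were matched to the RefSeq gene table of assembly GRCm38.p6, the same build as mm10, for 22992 rows and to GENCODE M21 for 126, and 168 rows had no name. Positions are printed 1-based. Transcript length, GC content and the share of 31-base words found at another locus were computed from the GENCODE M21 transcripts, and 98.95% of compared rows had values. Rows sharing 20% or more are treated as uncertain.

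For each of 34 gene lists fixed before the data were examined, the median log2 fold over compared members was placed among 10000 random lists of the same size matched on expression in 20 bins, for lists with at least 5 members. The percentile describes these group values and is not a p-value. Because PDGFA folds followed GC content, a cubic robust regression on GC, log2 length and log2 level was fitted, and list medians are also given without it. This step was added after the data were seen.

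Named genes follow a rule fixed beforehand. It takes the 15 largest rises and 8 largest falls per ligand, the 10 largest in each direction between ligands, up to 4 members of each list, and a fixed panel of growth factor response genes, receptors and reference genes. The rule asked that every treated library lie above every starved library. That was read here as intervals lying apart, and the smallest adjusted p as that of a z value made from the intervals. Dusp10, Prdx6b, Smad6, Bambi and the 2 genes with failed estimates lie outside the rule and were named after their values were seen. Alternatives covered the pseudocount, the minimum FPKM, the scaling, a minimum fold, the trend, shared and short rows, and z values from the intervals. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.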

Results

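The data were polyA RNA-seq profiles of mouse embryonic palatal mesenchyme cells (MEPMs), primary cultures of the connective-tissue precursors of the secondary palate taken from embryos at mid-gestation. Cells were starved of serum overnight and then left unstimulated (4 libraries), given 30 ng/mL PDGFA for 1 h (4 libraries), or given 50 ng/mL FGF1 with 1 µg/mL heparin for 1 h (3 libraries). PDGFA and FGF1 are ligands of receptor tyrosine kinases, the PDGF and FGF receptors, and heparin is a cofactor of FGF binding. The design sets each ligand against starved cells and the ligands against each other. It asks which genes respond within 1 h and whether the responses differ. In the labels only the FGF1 cells were given heparin, and no group had heparin alone. Effects of FGF1 and of heparin therefore cannot be told apart in any comparison with FGF1 below. The ligand doses differed too. Each group was represented by a single FPKM value per gene row, the authors' estimate over that group's libraries, with the lower and upper bound of its deposited interval. Values per library were not used here, so no replicate spread, SD or p-value between replicates stands behind any statement below. A row was called higher or lower only when the deposited intervals of the groups compared lay wholly apart, a rule chosen after the table's layout was seen. In brackets after an FPKM value stands its deposited interval. Sequencing depth was unknown. Of 23286 rows, 11702 had at least 1 FPKM in a group and were compared. In simulated groups of 11286 rows, most of them unchanged, with noise as wide as the intervals, the rule called 77 unchanged rows for PDGFA against starved cells, 41 for FGF1 against starved cells and 34 between the ligands. The 77 exceeds the 36 calls made with PDGFA in the data, so the intervals overstate the noise and these numbers do not give the share of chance calls.

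After 1 h of PDGFA, 36 rows were called higher than in starved cells and 0 were called lower. By size of the fold they were led by BC048507, listed at 0 FPKM in starved cells, and by Rps16, a row that shares sequence with copies. Many of the other called rows were immediate early genes, those that need no new protein for their transcription. Egr3, a zinc-finger transcription factor of the EGR family, went from 0.520 FPKM [0.215 to 0.807] to 26.5 [9.31 to 43.4], and Arc, an activity-regulated cytoskeletal gene, from 0.746 [0.428 to 1.07] to 19.9 [4.74 to 35.1]. Nr4a1, an orphan nuclear receptor, rose 13.1-fold, from 12.7 [9.32 to 16.0] to 166 [59.96 to 272]. Its relative Nr4a3 had a log2 fold of 2.56. Egr4, Fosb and Egr2 had log2 folds of 4.32, 3.78 and 3.05 from starved values under 1 FPKM. Junb, a subunit of the AP-1 factor, rose 5.96-fold and the stress-responsive factor Atf3 5.23-fold. Egr1 rose 4.37-fold, from 11.4 [8.52 to 14.2] to 49.7 [23.6 to 75.7]. Genes that restrain the signal rose as well. The ERK phosphatase gene Dusp5 rose 4.98-fold, the EGF receptor inhibitor Errfi1 4.05-fold, and Dusp1 3.06-fold. The prostaglandin synthase gene Ptgs2 rose 2.82-fold. Quantile normalization gave 33 rows higher and 74 lower in place of 36 and 0.

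Id1 and Id3, inhibitors of basic helix-loop-helix factors and familiar BMP target genes, also rose with PDGFA. Id1 went from 17.3 FPKM [10.3 to 22.0] to 76.3 [30.0 to 122], a 4.42-fold rise, and Id3 from 47.7 [30.1 to 57.5] to 134 [59.1 to 208], a 2.80-fold rise. The Id3 intervals lay just apart, and with a trend on GC content and length removed its log2 fold went from 1.476 to 1.29 and the call ended. The muscle actin genes Acta1 and Actc1 rose 5.07-fold and 7.51-fold, to 87.5 [25.6 to 149] and 10.96 [4.00 to 17.9] FPKM. Other skeletal muscle markers stood above the starved value too without intervals that lay apart: Mylpf had 2.49 FPKM in starved and 5.30 in PDGFA cells, and Tnni1 0.704 and 2.68. In the same group the Y-linked genes had lower values, such as Kdm5d with 3.68 FPKM in starved and 2.22 in PDGFA cells. Other rows with large rises shared sequence with copies elsewhere. Rps16 had 3.56 FPKM in starved and 134 in PDGFA cells, and 45.8% of its 31-base words occurred at another locus. Atp5l shared 69.7% and Rps29 39.2%, and all 3 are uncertain. In total, 82 compared rows had at least 1 FPKM with PDGFA and 0 in both other groups, and 71 of the 78 with a known length were under 200 nt.

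Over gene lists fixed before the data were examined, 12 of 27 immediate early transcription factors were called higher with PDGFA, and all 27 lay above the starved value, with a median log2 fold of 1.33. Of 26 other immediate early genes 4 were called higher (Arc, Ptgs2, Phlda1 and Errfi1), with a median of 0.88. The Phlda1 call ended with the trend removed, as its log2 fold went from 1.59 to 1.36. Of 19 MAPK phosphatases and receptor feedback inhibitors 3 were called higher (Dusp1, Dusp5 and Errfi1), and the median was 0.31. Of 20 TGF-beta and BMP response genes 3 were called higher (Id1, Id3 and Junb, of which Id3 lost its call with the trend removed), with a median of 0.61. For the cytoskeletal targets of the serum response factor SRF and its cofactor MRTF, 0 of 32 genes were called, while 27 of 32 had a higher value than in starved cells, with a median of 0.46. Examples are Cnn1, which encodes a calponin, at 112 FPKM in starved and 265 in PDGFA cells, Actg2, a smooth muscle actin, at 310.3 and 580.0, and Actb at 1552 and 2971. Each of these 5 medians lay above those of all 10000 random lists matched on expression, at percentile 100. The smooth muscle and pericyte markers (median 0.51, 0 of 11 called, percentile 99.99) and the skeletal muscle markers (median 0.89, 2 of 9 called, percentile 100) also lay high; Cnn1, Acta2 and Tagln stand in both the SRF-MRTF and the smooth muscle list. Of 30 lists compared, 12 lay outside the central 95% of random lists.

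PDGFA values followed transcript base composition. Among transcripts of at least 200 nt, the log2 fold was higher at higher GC content (Spearman 0.612 across 11464 rows, which are not independent replicates), from a median of −0.19 in the lowest GC octile to 0.24 in the highest. With FGF1 the correlation was 0.183. With transcript length in place of GC it was −0.17 for PDGFA and −0.249 for FGF1. After a smooth trend on GC, length and level was removed, the medians were 1.20 for immediate early transcription factors, 0.47 for TGF-beta and BMP response genes and 0.32 for SRF-MRTF cytoskeletal genes, each still at percentile 100. The deposited intervals were wider in PDGFA cells, with a median half-width of 49.5% of the FPKM, against 25.5% in starved and 34.6% in FGF1 cells.

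**Figure D1:**
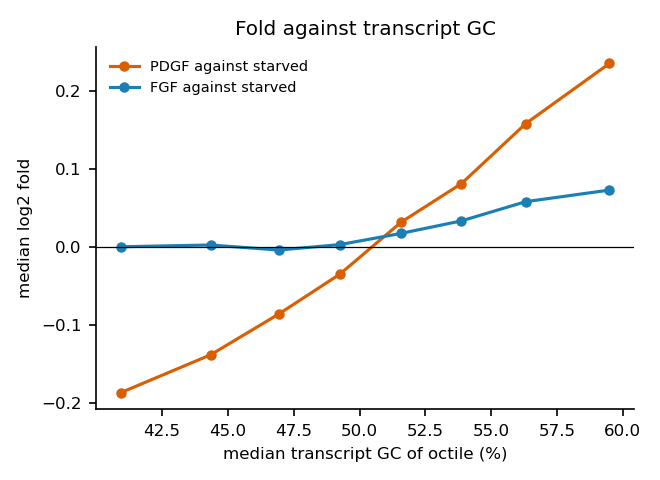
Median log2 fold of FPKM against starved cells (y axis) in 8 bins of transcript GC content (x axis, median percent of each bin), for PDGFA and FGF1. The PDGFA medians run from −0.19 to 0.24 and those of FGF1 from 0.00 to 0.07.

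FGF1 with heparin gave 63 rows called higher and 2 called lower than in starved cells. A z value from the intervals, centred and rescaled to its own spread and chosen after the data were seen, gave 266 higher and 199 lower. Egr3 went from 0.520 FPKM to 20.4 [12.3 to 28.5], Arc from 0.746 to 18.7 [12.5 to 24.99] and Egr2 from 0.519 [0.283 to 0.745] to 12.0 [7.86 to 16.2]. Nr4a1 rose 12.96-fold, to 164 FPKM [107 to 220]. Egr1 rose 10.2-fold, from 11.4 [8.52 to 14.2] to 116 [76.7 to 155]. Dusp5 rose 8.20-fold, Atf3 6.55-fold, Junb 5.92-fold, Errfi1 5.32-fold and Ptgs2 5.29-fold. Nppb, which encodes a natriuretic peptide, rose 4.83-fold, and the AP-1 genes Fosl1 and Fos rose 5.28-fold and 3.90-fold. Egr4 and Fosb had log2 folds of 2.86 and 2.70. Hbegf, the gene of a secreted ligand of the EGF receptor, went from 12.0 FPKM [8.80 to 15.1] to 57.3 [38.9 to 75.6], and Ereg from 2.02 [1.41 to 2.62] to 6.73 [4.53 to 8.91]. The cytokine gene Lif rose 2.27-fold. Both rows called lower were genes of membrane or matrix proteins. Kcnj2, a potassium channel, fell from 6.61 FPKM [5.10 to 8.12] to 3.00 [1.96 to 4.03], and Adamts15, a matrix protease, from 1.41 [0.996 to 1.83] to 0.648 [0.366 to 0.925]. With PDGFA both also stood below the starved value, but the intervals overlapped. Kcnj2 had 3.86 FPKM [1.99 to 5.74] there and Adamts15 0.648 [0.218 to 1.08], so the falls were not particular to FGF1.

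By list, 18 of 27 immediate early transcription factors were called higher with FGF1, with a median log2 fold of 1.61, and 12 of 26 other immediate early genes, with a median of 0.88. Among the latter, Trib1, which encodes a pseudokinase, rose 3.65-fold, Zfp36l2, of an mRNA decay factor, 2.92-fold, and Btg2, of an antiproliferative protein, 2.47-fold. Of 19 MAPK phosphatases and feedback inhibitors 7 were called higher, with a median of 0.44: Dusp1, Dusp4, Dusp5, Dusp6, Dusp10 (named after its values were seen), Errfi1 and Spry4. Dusp6, an ERK phosphatase, went from 10.6 FPKM [7.91 to 13.3] to 35.0 [23.95 to 46.1], and Spry4, a Sprouty-type inhibitor, from 4.17 [3.13 to 5.21] to 8.83 [6.06 to 11.6]. Of 14 FGF synexpression genes, a group co-expressed with FGF signalling in embryos, 3 were called higher (Dusp6, Spry4 and Phlda1). Their median was 0.15, at percentile 99.93. With PDGFA 1 of the 14 was called (Phlda1), and the median was 0.09 at percentile 87.69. Between ligands 0 were called. The median there was 0.03 at percentile 59.41, or 0.08 at percentile 97.8 with the trend removed. The ETS-factor genes of that list, Etv4 and Etv5, had 5.08 and 12.4 FPKM in starved and 5.90 and 14.1 in FGF1 cells, with overlapping intervals. Of 25 secreted growth factors 3 were called higher (Hbegf, Ereg and Lif), with a median of 0.14 at percentile 99.92. With PDGFA 0 of these 25 were called, and their median was 0.22 at percentile 99.96. Between ligands it was 0.07, at percentile 85.7. Of 21 YAP-TEAD targets 3 were called higher (Nuak2, F3 and the connective tissue growth factor gene Ccn2), with a median of 0.11 at percentile 94.1, or 0.08 at percentile 99.9 with the trend removed. With PDGFA 0 of these 21 were called, and their median was 0.21 at percentile 99.29, or 0.10 at percentile 98.87 with the trend removed. Between ligands it was −0.01, at percentile 23.78. Ccn2 lost its call without the trend, its log2 fold going from 1.16 to 1.05. Of 20 TGF-beta and BMP response genes 3 were called higher, Junb and Ccn2 among them, with a median of 0.20 at percentile 100. The SRF-MRTF cytoskeletal genes had a median of 0.21 at percentile 100, with 0 of 32 called, where random lists had 0.11; with the trend removed it was 0.09, also at percentile 100. Hes1 and Lfng, of the Notch pathway, rose 2.37-fold and 3.06-fold. The clock-related genes Bhlhe40 and Per1 rose 3.11-fold and 1.87-fold. All 20 cholesterol synthesis genes lay above the starved value and 0 were called, with a median of 0.24 at percentile 100, or 0.18 with the trend removed. Insig1 had 92.6 FPKM in starved and 145 in FGF1 cells. Of 30 lists, 16 lay outside the central 95% of random lists.

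**Figure D2:**
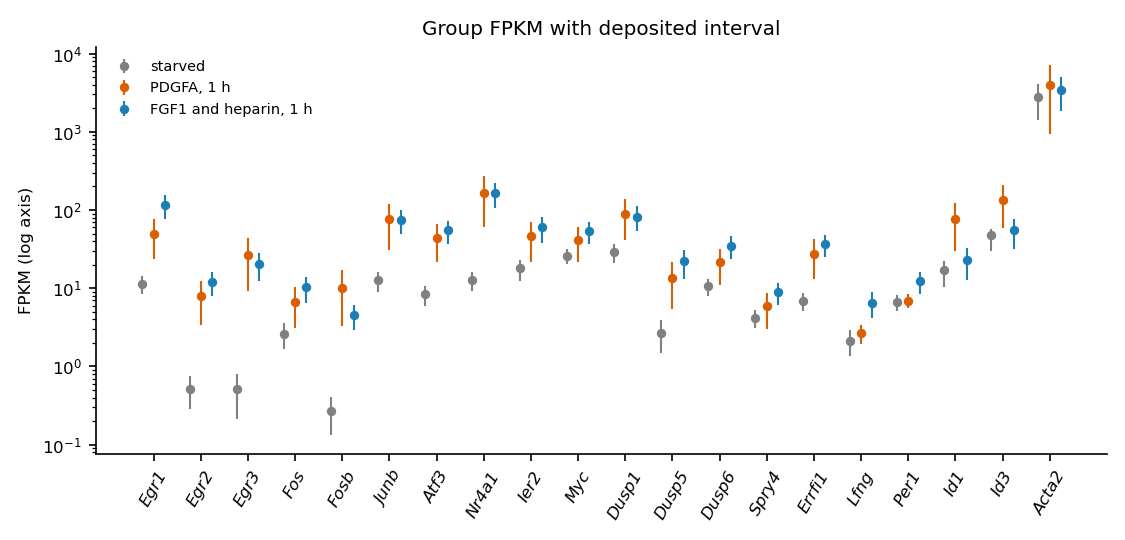
FPKM of 20 genes (log y axis) in starved, PDGFA-treated and FGF1-treated cells. Points are the authors' group values and bars their deposited intervals. Egr1 stands at 11.4, 49.7 and 116 FPKM, and Id1 at 17.3, 76.3 and 23.0.

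Set directly against each other, the ligands differed in 14 rows: 3 were called higher with FGF1 and 11 higher with PDGFA. Egr1 had 116 FPKM [76.7 to 155] with FGF1 and 49.7 [23.6 to 75.7] with PDGFA, a 2.33-fold difference. Lfng, a glycosyltransferase gene of the Notch pathway, had 6.55 [4.17 to 8.92] and 2.65 [1.93 to 3.37], and Per1, a clock gene, 12.3 [8.34 to 16.3] and 6.95 [5.56 to 8.33]. In PDGFA cells the deposited intervals of Lfng and Per1 were unusually narrow for that group: the half-width was 27.2% of the FPKM for Lfng and smaller for Per1. With median-of-ratios scaling the calls of Egr1 and Per1 ended, leaving 1 row called higher and 11 lower with FGF1. Quantile normalization gave 64 higher and 9 lower. Of these 64 rows, 61 were under 1 FPKM with PDGFA as deposited. The 64 had a median log2 fold of 0.232 as deposited, and their PDGFA values were multiplied by a median factor of 0.333. Among the rows higher with PDGFA, Actc1 had 10.96 FPKM [4.00 to 17.9] against 1.49 [0.712 to 2.25] with FGF1. The others were Rps16, Atp5l, BC048507, 4930503E24Rik, E130201H02Rik, Aldoart2, Pin1rt1, Gm5779, Gm4907 and Prdx6b. Of these 11 rows, 10 shared at least 3% of their 31-base words with another locus, against 17.3% of all compared rows, and 6 were listed at 0 in both other groups. Only Rps16 and Atp5l shared 20% or more. The last of the names, Prdx6b, and the 3% limit were taken up after the values were seen.

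By list, contractile genes had lower values with FGF1 than with PDGFA. Of the 32 SRF-MRTF cytoskeletal genes 0 were called and 7 had a higher value with FGF1 than with PDGFA, and the median log2 fold of FGF1 against PDGFA was −0.19, at percentile 0, or −0.20 with the trend removed, also at percentile 0. Cnn1 had 265 FPKM with PDGFA and 142 with FGF1, Actg2 580.0 and 379, and Actb 2971 and 2108, with overlapping intervals. None of the 11 smooth muscle and pericyte markers was higher with FGF1 (median −0.24, percentile 0.115). For the 9 skeletal muscle markers the median was −0.79, with 1 called (Actc1). The sex-linked genes, most of them Y-linked, had a median of 0.61 at percentile 100. Wnt pathway genes (median −0.13, percentile 0.940) and palate and craniofacial transcription factors (median −0.11, percentile 0.0900) lay lower with FGF1, as did S phase and mitosis genes (−0.08, 2.09) and 5 endothelial markers (−0.33, 0.395). With the trend removed these medians were −0.10 for Wnt pathway genes, −0.06 for palate and craniofacial transcription factors, −0.11 for S phase and mitosis genes and −0.18 for endothelial markers, at percentiles 1.12, 0.890, 0 and 1.995. Those of smooth muscle, skeletal muscle and sex-linked genes were −0.21, −0.70 and 0.43. Notch pathway genes (median 0.27, percentile 100), cholesterol synthesis genes (0.16, 99.1), p53 targets (0.17, 99.6), MAPK phosphatases and feedback inhibitors (0.13, 99.4) and other immediate early genes (0.12, 98.4) lay higher. The reference (housekeeping) genes also lay higher, with a median of 0.17 at percentile 98.1, or 0.03 at percentile 75.7 with the trend removed. Without the trend the medians were 0.22 for Notch pathway genes, 0.16 for cholesterol synthesis genes, 0.10 for p53 targets, 0.09 for MAPK phosphatases and feedback inhibitors and 0.09 for other immediate early genes, each still outside the central 95% of random lists. The immediate early transcription factors had a median of 0.01, at percentile 39.4, with 14 of 27 genes higher with FGF1, and a median of 0.13 at percentile 100 with the trend removed. Id1 and Id3 had 23.0 and 55.5 FPKM with FGF1, and their intervals overlapped those with PDGFA. Of 30 lists, 14 lay outside the central 95% of random lists.

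**Figure D3:**
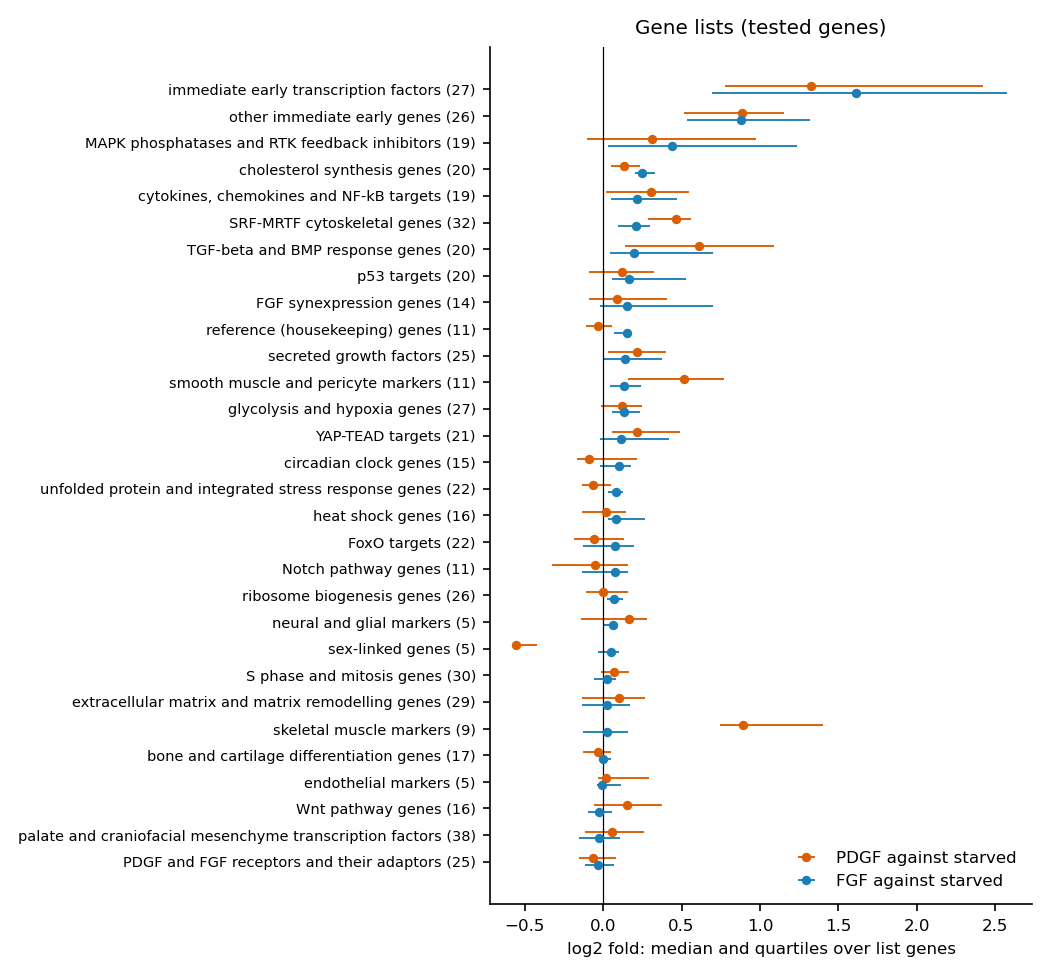
Median (point) and quartiles (bars) of the log2 fold over the compared genes of each of 30 gene lists (number of genes in parentheses), for PDGFA and FGF1 against starved cells. Immediate early transcription factors reach 1.33 and 1.61, SRF-MRTF cytoskeletal genes 0.46 and 0.21.

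Of the 36 rows called higher with PDGFA and the 63 with FGF1, 21 were in both lists, where independent lists would share 0.194. Both comparisons use the same starved cells. Groups simulated without change against those cells shared 3.16 rows when the noise was as wide as the intervals (100 simulations). With noise only as wide as the observed scatter they shared 0 (100 simulations). That 0 gives no information, because the scatter was narrower than the intervals, which had to lie apart for a call. Of the 21 shared rows, 13 had the higher value with PDGFA (Egr3, Egr4 and Fosb among them) and 8 with FGF1 (Egr1, Dusp5 and Ptgs2 among them). Only Egr1 had PDGFA and FGF1 intervals that lay apart. All 63 rows called higher with FGF1 had a PDGFA value above the starved value, with median log2 folds of 1.43 with FGF1 and 1.07 with PDGFA. Of the 36 rows called higher with PDGFA, 30 had an FGF1 value above the starved value, and the 33 of at least 200 nt with under 20% shared sequence had medians of 2.11 with PDGFA and 1.49 with FGF1. Each set was selected on its own ligand, which favours that ligand's median. Of the 42 rows called higher with FGF1 alone, 2 differed from PDGFA (Lfng and Per1). Of the 15 called with PDGFA alone, 11 differed from FGF1. These are the 11 rows named above as higher with PDGFA than with FGF1. Of them, 10 shared at least 3% of their 31-base words with another locus, and 6 stood at 0 in starved and FGF1 cells. Over 10768 rows of at least 200 nt with under 20% shared sequence, the log2 folds of the ligands had a Pearson r of 0.609. Their covariance was 0.0395. The simulations with interval-wide noise gave 0.224 and 0.0575, so the r lay above them and the covariance below. Those with scatter-wide noise gave 0.555 and 0.0154. That noise was estimated from these same folds, so its values restate the data and do not stand for unchanged groups. How much of the correlation comes from the shared starved cells cannot be told, since those could not be split. The r was also computed with the trends on GC content and length left in. These ran in the same direction for PDGFA and FGF1 (Spearman 0.612 and 0.183 with GC, −0.17 and −0.249 with length). Their part in the r was not tested.

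**Figure D4:**
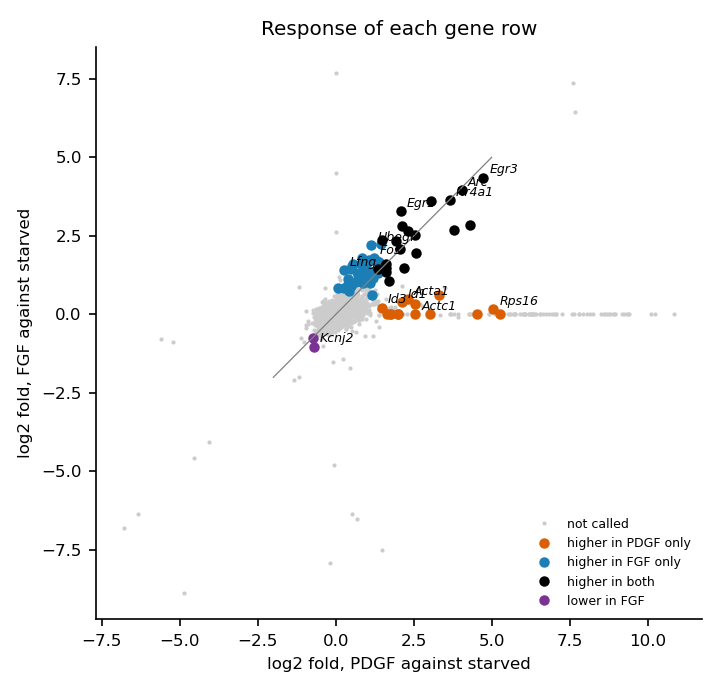
Log2 fold of each of 11702 rows with PDGFA (x axis) and FGF1 (y axis) against starved cells, coloured by call, with the line of equal folds. All 63 rows called higher with FGF1 lie to the right of 0, and the 82 rows seen with PDGFA alone lie on the horizontal at 0.

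Of 25 PDGF and FGF receptor and adaptor genes 0 were called with either ligand. Their median log2 fold was −0.03 with FGF1, at percentile 0.420, or −0.07 at percentile 0.130 with the trend removed, and −0.07 with PDGFA, at percentile 6.71. Pdgfra, the PDGFA receptor gene on chromosome 5, had 3.87, 3.52 and 2.46 FPKM in starved, PDGFA and FGF1 cells, and Pdgfrb 71.1, 63.9 and 70.9. Fgfr1 had 43.1, 46.8 and 44.9 FPKM, and Fgfr2 10.7, 13.3 and 11.5. Of 38 palate and craniofacial transcription factors 0 were called. Twist1 had 60.1, 94.4 and 62.4 FPKM, Snai1 14.8, 23.96 and 20.6, Dlx2 8.29, 13.52 and 11.04, and Mn1 17.0, 15.3 and 13.2. Genes of S phase and mitosis (30), ribosome biogenesis (26) and bone and cartilage differentiation (17) had 0 calls with either ligand. Epithelial markers had 3 genes at 1 FPKM or more, macrophage and leukocyte markers 2 and erythroid markers 0, too few to compare. Gapdh, which has many near-identical copies, was listed at 0.11, 0.15 and 0.17 FPKM and fell below the minimum. Col1a1 was listed at 0 in every group with a failed estimate, and so gives no value for this collagen gene.

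Several of the leading genes lie at these mm10 positions. Egr1 spans chromosome 18 from 34861207 to 34864956, Egr3 chromosome 14 from 70077445 to 70080157, Fosb chromosome 7 from 19302696 to 19310045, and Nr4a1 chromosome 15 from 101266846 to 101274794. Dusp6 lies on chromosome 10 from 99263231 to 99267489, Hbegf on chromosome 18 from 36504927 to 36515805, and Lfng on chromosome 5 from 140607341 to 140615545. Id1 lies on chromosome 2 from 152736274 to 152737410 and Id3 on chromosome 4 from 136143822 to 136145392.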

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

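All tests in this part were chosen after the results were seen, and the differences between ligands rest on intervals that lie apart, not on a test between replicates.

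Between ligands, 14 rows differed. The log2 fold of FGF1 against PDGFA was 1.21 for Egr1, 1.16 for Lfng and 0.78 for Per1. It was −5.27 for BC048507, −4.87 for Rps16, −4.53 for 4930503E24Rik, −2.99 for E130201H02Rik, −2.70 for Atp5l, −2.53 for Actc1, −1.99 for Aldoart2, −1.99 for Pin1rt1, −1.77 for Gm5779, −1.74 for Gm4907 and −1.66 for Prdx6b. Outside the compared rows, Thbs1, a matrix glycoprotein gene, had 1996.73 FPKM with PDGFA [470.3 to 3522.97] and failed estimates in starved and FGF1 cells, so that no fold can be given.

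The first pattern is the set of rows seen or called higher with PDGFA alone. There were 82 rows at 1 FPKM or more with PDGFA and at 0 in both other groups, against 3 such rows for FGF1 and 4 for starved cells. Among the 78 with a known length, 91.03% were under 200 nt, against 0.993% of compared rows, which is consistent with short rows having been estimated differently in the PDGFA group. The 47 genes that span any of those short rows had a median log2 fold of 0.001342 with PDGFA and an upper quartile of 0.22, so their polyA RNA was not raised as a set. The level of polyA RNA does not measure transcription, and how many of the short rows such genes span was not counted. Raised transcription of the spanning genes was therefore not excluded. The 11 rows called higher with PDGFA than with FGF1 shared a median of 9.58% of their 31-base words with another locus, above 99.98% of matched random lists. Reads shared with copies may account for part of them, though not for Actc1 at 0.83%. As a whole, however, compared rows with shared sequence did not lie higher with PDGFA. Their median log2 fold of FGF1 against PDGFA was 0.10 at 5 to 20% shared sequence (891 rows). It was 0.15 at 20 to 50% (492 rows) and 0.22 at 50% or more (220 rows). Without rows of 20% or more, or under 200 nt, 9 of the 11 were still called.

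The second pattern is the lower level of SRF-MRTF cytoskeletal genes with FGF1 than with PDGFA. A trend with GC content and length is argued against as the whole cause, since the median without it was −0.1979 with an upper quartile of −0.01. Shared reads between paralogs are argued against by a median of −0.1949 over the 28 genes under 20% shared sequence. More skeletal muscle cells with PDGFA could not be excluded: of 8 contractile genes of muscle the largest excess over FGF1 was 62.92 FPKM, that of Acta1, which was called with PDGFA. The smallest excess was 17.7 FPKM among 8 non-muscle members picked by name, Actb with 35.3% shared sequence among them. Of all 32 list members, 7 had a higher value with FGF1, so the whole list has no such positive minimum. Against more muscle cells, the 6 muscle genes other than Acta1 and Actc1 gained at most 3.077 FPKM, 3 of them under 1 FPKM in every group. An effect of the ligand, of the heparin given with FGF1, a share of muscle cells and another difference between cultures stay open.

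The third pattern is that skeletal muscle markers lay higher and Y-linked genes lower with PDGFA than in the other groups. The GC and length trend is argued against as the whole cause for both, though it accounts for part of the Y-linked shift: without it the 6 muscle markers other than Acta1, Actc1 and Des had a median log2 fold of 0.7251, from 0.77 with it, and Ddx3y, Eif2s3y, Kdm5d and Uty a median of −0.3511, from −0.56 with it, with all 4 below 0. Another mix of embryos or cells could not be settled. Xist had a log2 fold of 0.132 with an interval from −0.85 to 1.12, and of 0.307 with the trend removed. With 1 value per group a culture difference and the ligand cannot be told apart here.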

How the results depend on the processing

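No paired analysis was possible because the columns hold 1 value per group and no replicate. For the same reason the limma settings, the replicate block, leaving out libraries, splits of the starved libraries, other splits of the samples and camera's settings were not run. The pseudocount does not enter the calls, so trying 0.1 and 1 tested only folds and list medians. A 2-fold minimum left each count of calls and the overlap within 1.5 times, as did scaling by median of ratios and dropping the filter. Called genes named by the rule kept their direction under median of ratios and trend removal. Egr1 and Per1, FGF1 against PDGFA, lost their call with median of ratios. Trend removal ended 4 calls of PDGFA (Id3 and Phlda1 among them) and 4 of FGF1 (Ccn2 and Dnajb1 among them), and added 2 to each.

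A minimum of 5 FPKM gave 8 rows different between ligands in place of 14, since fewer rows were compared. Quantile normalization gave 107 rows changed by PDGFA (33 higher, 74 lower) and 73 different between ligands. The added falls come from its construction, as rows at 0 in the other groups enter the common distribution. The PDGFA values of the 74 rows were multiplied by a median factor of 0.333, 71 of them under 1 FPKM. For the 64 rows higher with FGF1 than with PDGFA the median factor was also 0.333, with 61 under 1 FPKM. The settings that follow were chosen after the data were seen. A z value from the intervals at an adjusted p under 0.05 gave 122 rows for PDGFA. Between ligands it gave 105, of which 5 were higher and 100 lower with FGF1. At 0.01 it gave 112 and 100. Without short and shared rows, which also changes the adjustment, it gave 28 and 9; the cause was not tested. Rescaled to its own spread, z gave 271 rows for PDGFA (251 higher, 20 lower) and 465 for FGF1 (266 higher, 199 lower). It gave 248 between ligands (51 higher and 197 lower with FGF1) and 90 higher in both. The nearly one-sided direction of the FGF1 calls did not hold there. At an adjusted p under 0.05 without rescaling, FGF1 had 51 higher and 11 lower. Removing the trend turned the FGF1 median of extracellular matrix genes from 0.02 to −0.10, and the trend itself is what was removed. That list lay below nearly all random lists both ways, at percentile 0.11 before and 0 after. Trend removal moved 13 of 90 list medians outside the central 95% of random lists and 3 inside. The number of lists outside them stayed within 1.5 times in each comparison under all settings tried. Depth is unknown, and the wider PDGFA intervals limit what could be called there.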

Other observations

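Of the 20 TGF-beta and BMP response genes, 8 had a higher value with FGF1 than with PDGFA, and the median log2 fold of FGF1 against PDGFA was −0.07, at percentile 4.91 of random lists, or 0.01 at percentile 56.97 with the GC and length trend removed. The intervals of the members that follow overlapped, and Smad6 and Bambi were picked after their values were seen. Id2 had 16.4 FPKM in starved, 29.7 in PDGFA and 15.6 in FGF1 cells, Smad6 had 6.31, 9.93 and 6.04, Atoh8 had 1.55, 4.53 and 1.26, and Bambi had 1.62, 2.72 and 1.84. Smad7, an inhibitor shared by TGF-beta and BMP signalling, had 7.45, 12.7 and 13.3 FPKM.

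Against starved cells, 16 of 29 extracellular matrix genes had a higher value with PDGFA (median log2 fold 0.10, percentile 73.5). So did 6 of 17 bone and cartilage differentiation genes (median −0.03, percentile 27.3), and 0 of either list were called. With FGF1, 16 of the 29 extracellular matrix genes had a higher value and 1 was called. Their median of 0.02 lay at percentile 0.11, where random lists had 0.10, and was −0.10 at percentile 0 with the trend removed. The genes that follow had overlapping intervals. Col10a1 had 36.6 FPKM in starved, 18.5 in PDGFA and 39.2 in FGF1 cells, and Postn, the periostin gene, had 697, 407 and 578. Sfrp2, an extracellular Wnt modulator, had 81.5, 135.7 and 65.9 FPKM.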
